A study of Carassius auratus with 6 samples.

How the data were processed

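RNA sequencing measured gene expression in whole eyeballs of goldfish (Carassius auratus) with normal eyes and with celestial eyes, a fancy breed whose eyes point upward. There were 6 libraries, 3 titled C and 3 titled R. The labels say that the fish were 1 winter year old, that the normal-eyed and celestial-eyed fish came from different farms, that eyes were frozen in liquid nitrogen and extracted with Trizol, and that TruSeq libraries were made from 3 µg of total RNA. The labels disagree on which letter is which. The characteristics of the samples call C normal and R celestial-eyed, while the design text of the series calls R normal and C celestial-eyed. The groups are therefore named by their letters, the phenotype of each letter is left open, and every direction is given as C against R. Farm and phenotype are confounded, since each group came from 1 farm. The labels name 3 fish per group and do not say which library came from which fish, so p-values measure the spread between these libraries.

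The deposited table holds FPKM (reads counted per kilobase of gene, scaled to the total of the library) for 56251 gene models, with their positions, lengths and best protein matches. The 2 tables of single groups repeat its values exactly. Bowtie 0.12.5, TopHat2 2.0.9 and DESeq 1.10.1 are named, per the submitters' processing notes, without their roles. These notes also name a pig genome build, which does not match the goldfish gene identifiers and the 50 chromosomes in the files. The genome assembly behind the coordinates, the counting tool and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping antisense gene may not be separated. Goldfish carry duplicated genomes, so reads of near-identical copies may be split between gene models in ways that cannot be checked here.

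Multiplying each deposited FPKM value by gene length gave whole multiples of 1 step per library for 100% of values (tolerance 0.01 of a read). The recovered totals were 9444623, 9806435 and 11017539 reads for C1, C2 and C3, and 9829134, 10450126 and 11317200 reads for R1, R2 and R3. The highest total was 1.20 times the lowest. At this depth 3 reads in a gene of 1 kb correspond to 0.265 to 0.318 FPKM. Read intervals and floors below cover counting error only. A floor of 3 reads over the 3 libraries of a group was used for genes with no read in a group.

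Names came from the goldfish RefSeq table of assembly ASM336829v1, used for names only, where the accession in the files carried a symbol, and otherwise from the gene name of the best Swiss-Prot match. Of the 56251 models, 44177 had a Swiss-Prot match, 43028 a Swiss-Prot gene name, 38020 an accession found in the RefSeq table and 9538 a goldfish symbol there. Names taken from best matches group related genes, and several models can carry 1 name.

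Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 33907 genes, holding 99.0% of the reads in the library where they held least. The test was limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3 on log2(FPKM + 1), with group as the only term and Benjamini-Hochberg adjustment. A gene counted as changed at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The test planned for count tables was not used because the files hold FPKM. Simulated data of the C against R comparison had 200 genes planted as changed and the same read dispersion, 0.03, for every gene (33823 genes tested). The test recovered 41 of 99 genes planted at 2-fold and 97 of 98 planted at 4-fold, none with the wrong sign, and called 16 unchanged genes. The real data had many more changed genes and a spread that differed between genes, so these rates need not hold for them.

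There were 31 gene lists with 1377 symbols, fixed before the data were examined together with the grouping, the tests and the rule for named genes. A gene was a member if its symbol was listed, allowing paralog suffixes (a, b, l, s, digits or -like). Swiss-Prot entries without a gene name were matched by entry name. Lists were tested with camera (2-sided, inter-gene correlation preset to 0.01) over the lists, and again with an estimated correlation and with fry, a rotation test. The lists covered rod phototransduction, cone phototransduction, photoreceptor outer segment and synapse, visual cycle and pigment epithelium, bipolar with amacrine and horizontal cells, ganglion cells, Mueller glia, lens, collagens, proteoglycans and other matrix, matrix remodelling, cartilage and sclera, cornea and surface epithelium, melanin, iridophores and xanthophores, endothelium and pericytes, red blood cells, skeletal muscle, leukocytes, complement, interferon response, heat shock, immediate early genes, circadian clock, eye size, intraocular pressure, eye field regulators, cell cycle, glycolysis and hypoxia, the mitochondrial respiratory chain and cytosolic ribosomal proteins.

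The named genes follow 3 rules. Every gene matched to lrp2 is named, whatever its result. Among changed genes with a mean of at least 5 FPKM over the 6 libraries, a name, and no overlap between the C and R libraries, the 8 with the largest positive and the 8 with the largest negative log2 fold change are named. For each list called by camera the 2 changed members with the smallest adjusted p are named, and for each other list with at least 3 changed members the 1 with the smallest. FPKM values are means ± SD over the 3 libraries of a group, and each log2 fold change is given with its standard error (SE).

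The alternatives were pseudocounts of 0.1 and 0.01, quantile normalization, a median log2 ratio set to 0 in each library, no filter on low values, a mean of at least 5 FPKM, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a 2-fold minimum, and list members matched by exact symbols. The fits added after seeing the data were limma-voom on the recovered reads, and the test on FPKM summed over genes that share a name. Shares of reads in crystallins, globins, keratins and collagens were also computed after seeing the data and compared with a 2-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.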

Results

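Expression was measured in the eyeballs of 6 goldfish libraries, 3 titled C and 3 titled R, to compare normal with celestial eyes. The letters stand for the 2 phenotypes and the 2 farms, and which letter is the celestial-eyed group is left open because the labels contradict each other. Libraries held 9444623 to 11317200 reads counted in genes, with 44215 to 46327 gene models above 0 in each.

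The libraries parted by letter. The first principal component held 64.1% of the variance and separated the C from the R libraries. Correlations of log2(FPKM + 1) were 0.946 to 0.966 between libraries of the same letter and 0.862 to 0.884 between letters. The library C3 stood apart from C1 and C2 on the second component, which held 14.7% of the variance.

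**Figure D1:**
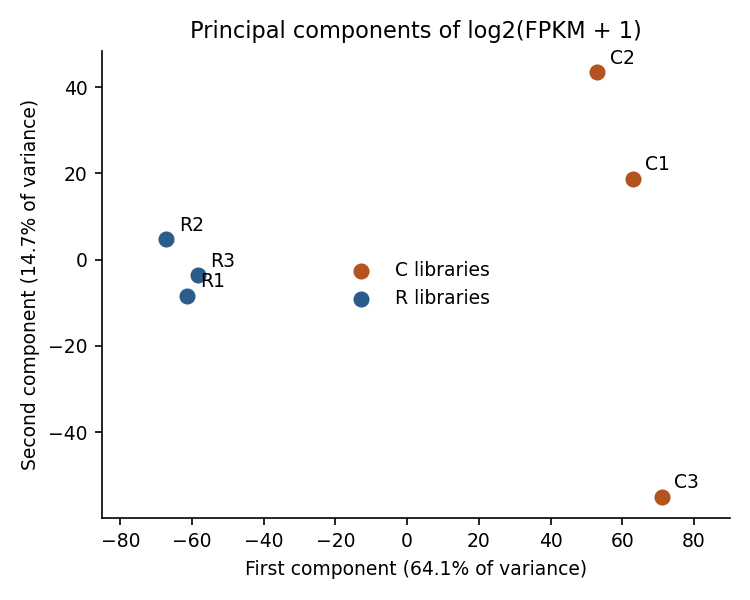
Each point is 1 library, placed by its first and second principal components over the 33907 tested genes (axes in component units, with percent of variance). The C libraries lie at the right and the R libraries at the left, and C3 lies away from C1 and C2 along the second component.

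Of 33907 genes tested, 6864 (20.2%) changed between C and R, 2939 higher and 3925 lower in the C libraries (limma, Benjamini-Hochberg adjusted). At least 2-fold changes were seen for 3195 of them, 1354 higher and 1841 lower. The 3 C and the 3 R libraries did not overlap for 41.4% of tested genes, where chance gives 10%. The balance of directions depended on scaling: 42.8% of changed genes were higher in C with values as deposited, and 52.4% (3771 against 3422) with the median log2 ratio set to 0, which removed a median shift of -0.09. Leaving out a library lowered the count most for C1 (4145 genes), R1 (3992), R2 (3557) and R3 (4520), and the count without C3 was 6404.

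The gene lrp2a, which encodes megalin, a large endocytic receptor whose loss enlarges the eye in zebrafish, was lower in the C libraries. Its main model, Cau.09G0011810 on chromosome 9 from 28526035 to 28638453 (plus strand, assembly not named in the files), had 7.38 ± 1.77 FPKM in C and 15.9 ± 2.23 FPKM in R (SD, n = 3 each). The log2 fold change was -1.03 (SE 0.19, limma adjusted p = 0.00937), and all 3 C libraries lay below all 3 R libraries. A second lrp2a fragment on chromosome 9 and the 4 models of lrp2b on chromosome 12 were below the test's minimum, the highest at 0.284 ± 0.141 FPKM in C and 0.232 ± 0.164 in R.

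Among the genes with the largest increases in C were both chains of an MHC class II molecule, which presents antigen to helper T cells. The beta chain gene (best match h2-eb1, Cau.33G0010360, chromosome 33, 22180599 to 22183288) had 59.0 ± 9.89 FPKM in C, and 2 reads over the R libraries, a read ratio of 1657 (95% exact counting interval 458 to 13690). Its neighbour, the alpha chain gene hla-dpa1 (Cau.33G0010370, 22186466 to 22190891), had 49.2 ± 8.41 FPKM in C and no read in R, at least 701-fold higher in C against the floor of 3 reads over the group. On the log2(FPKM + 1) scale these differed by 5.85 (SE 0.16) and 5.63 (SE 0.16), each with a limma adjusted p of 2.37e-06. The gene of neuromedin-U, nmu, a signalling peptide, rose from 0.303 ± 0.18 FPKM in R to 44.1 ± 12.4 in C (log2 fold change 5.09, SE 0.22, adjusted p = 1.62e-05 by limma). No other tested gene carried any of these 3 names. Names can come from best matches, so related genes under other names, such as further class II genes, are not covered by this. On chromosome 33, which holds the class II pair, 26.25% of tested genes changed, against 20.2% of all. Same-name copies of kdm5c and rbm39 numbered close to the pair moved in opposite directions, while the aebp1 copies Cau.33G0010830 and Cau.33G0010840 both fell. Whether the class II models stand for alleles or local duplicates that differ between the stocks was not tested.

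Several of the other large increases were in single copies of genes that have further copies. A copy of es1, encoding a mitochondrial protein, had 219 ± 65.7 FPKM in C and 0.665 ± 0.275 in R (log2 fold change 7.02, SE 0.22), but the FPKM summed over all es1 models was 1977 ± 498 in C and 1741 ± 235 in R. A copy of the ribosomal protein gene rps3a had 0.775 ± 0.439 FPKM in R and was higher in C by a log2 fold change of 6.86 (SE 0.19), with sums of 1052 ± 83.4 in C and 1124 ± 107 in R. The copy of marcksl1a at Cau.38G0011200, encoding a membrane-bound actin regulator, had 74.5 ± 8.82 FPKM in C and 0.442 ± 0.175 in R (5.71, SE 0.15), with sums of 194 ± 26.4 and 139 ± 4.28. A copy of galectin-3, lgals3, had 46.1 ± 22.1 FPKM in C and 0.498 ± 0.165 in R (4.87, SE 0.32), with sums of 178 ± 28.6 and 151 ± 23.1. For cox6a1, a subunit of cytochrome c oxidase, the copy on chromosome 33 had 184 ± 36.2 FPKM in C and 6.78 ± 1.16 in R (4.57, SE 0.18), and the log2 ratio of the sums was 1.06. Limma adjusted p-values of these copies lay between 2.37e-06 and 0.000118.

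The largest decreases in C were led by a short model matched to papilin, ppn, and described in the files as a collagen XXVIII-like chain (Cau.38G0011110, chromosome 38, 28522038 to 28522229). It had 319 ± 93.4 FPKM in R and 2 reads over the C libraries, a read ratio of 918 (95% exact counting interval 254 to 7587). The lens galectin grifin had 63.8 ± 16.3 FPKM in R and 3 reads in C at this copy, a ratio of 302 (103 to 1469), while another copy rose. The grifin sums were 1032 ± 126 in R and 635 ± 153 in C. A CLK4-like kinase gene had 43.8 ± 6.34 FPKM in R and 1 read in C, a ratio of 719 (129 to 28450). A high mobility group B2-like gene, coding for a chromatin protein, had 79.5 ± 12.7 FPKM in R and 0.899 ± 0.21 in C. The log2 fold changes of these genes were -7.87 (SE 0.24), -5.73 (SE 0.21), -5.39 (SE 0.16) and -5.40 (SE 0.16). The ppn model lies on chromosome 38 near the marcksl1a copy that rose (28845234 to 28848506). A col6a3 fragment that fell lies between them (28728996 to 28729145). These need not be separate changes, which was not tested.

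The other large decreases were, as for grifin, in copies of genes with a further copy that rose. A copy of nupr2, a nuclear stress protein gene, had 59.4 ± 4.34 FPKM in R and 0.587 ± 0.326 in C, while the sum over its copies was 71.1 ± 4.89 in R and 68.8 ± 1.72 in C. A copy of ndfip2, an adaptor of ubiquitin ligases, had 33.0 ± 6.48 FPKM in R and 0.12 ± 0.0851 in C, with sums of 79.8 ± 2.99 and 94.4 ± 5.18. For atp6v0e2, a proton pump subunit, the copy had 30.6 ± 6.55 FPKM in R and 0.194 ± 0.336 in C, and the sums were 39.6 ± 7.48 and 43.7 ± 9.93. The gamma-crystallin crygnb had 2020 ± 261 FPKM in R and 85.7 ± 47.1 in C at this copy, and 2840 ± 187 against 1769 ± 590 in sum. Their log2 fold changes were -5.27 (SE 0.17), -4.91 (SE 0.18), -4.74 (SE 0.23) and -4.72 (SE 0.42), with limma adjusted p-values of 3.63e-06 to 0.000483. Of the 16 genes with the largest changes, 8 had another gene of the same name that changed in the opposite direction.

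**Figure D2:**
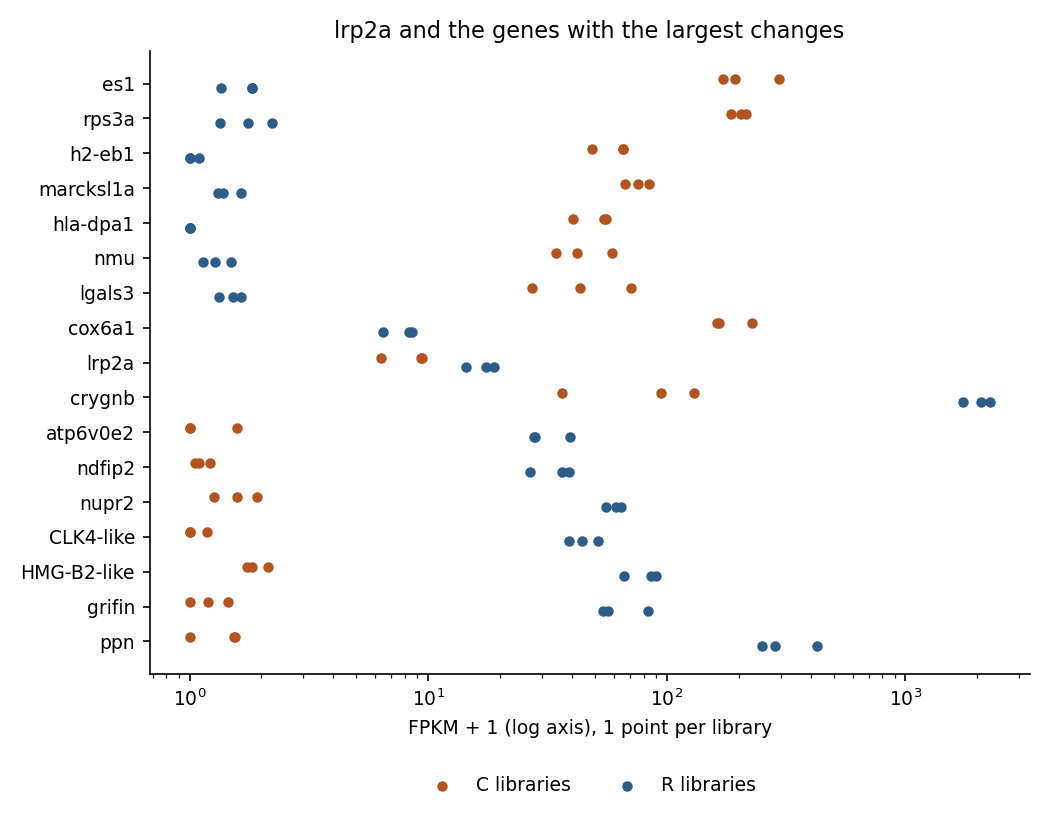
FPKM + 1 on a log axis for lrp2a and the 16 genes with the largest changes (8 per direction), 1 point per library, C and R in different colours. For every gene shown, the 3 C points and the 3 R points do not overlap; genes with no read sit at 1.

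Lens and surface epithelium genes were lower in C. Of 81 lens genes tested, 44 fell and 3 rose (55 and 3 adjusted over the list alone), with a mean log2 fold change of -0.90. Camera called the list lower (adjusted p = 1.82e-10 with the preset correlation, 1.09e-17 to 7.5e-08 over the other settings with that correlation), and the adjusted p = 0.786 with an estimated correlation. The 2 members with the smallest p were grifin and crygnb, described above. Crystallins, the main proteins of the lens, took 5.37% ± 1.85 of reads in C and 9.54% ± 0.165 in R (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The C libraries differed among themselves, with 5.24% in C1, 3.59% in C2 and 7.28% in C3.

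Of 44 cornea and surface epithelium genes, 24 fell and 3 rose in C (29 and 4 adjusted over the list alone), with a mean log2 fold change of -1.12. Camera gave an adjusted p of 3.57e-07 (4.18e-09 to 6.29e-05 over the other settings with that correlation), and the adjusted p = 0.786 with an estimated correlation. A minor copy of the keratin gene krt17 had 0.114 ± 0.0608 FPKM in C and was higher in R (log2 fold change -3.39, SE 0.25, limma adjusted p = 0.000222). This copy is described as keratin 19-like, so its name is uncertain. The sums over the krt17 name, which include it, were 137.4 ± 76.1 FPKM in C and 478.7 ± 233 in R. The epithelial adhesion molecule gene epcam had 0.58 ± 0.375 FPKM in C and 9.9 ± 1.12 in R at this copy (-2.81, SE 0.21, limma adjusted p = 0.000237). Another epcam copy changed in the opposite direction, and the sums were 179 ± 92.3 in C and 313 ± 37.2 in R. Keratins together took 0.397% ± 0.0413 of reads in C and 0.904% ± 0.223 in R (n = 3 each, exact permutation p = 0.1).

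**Figure D3:**
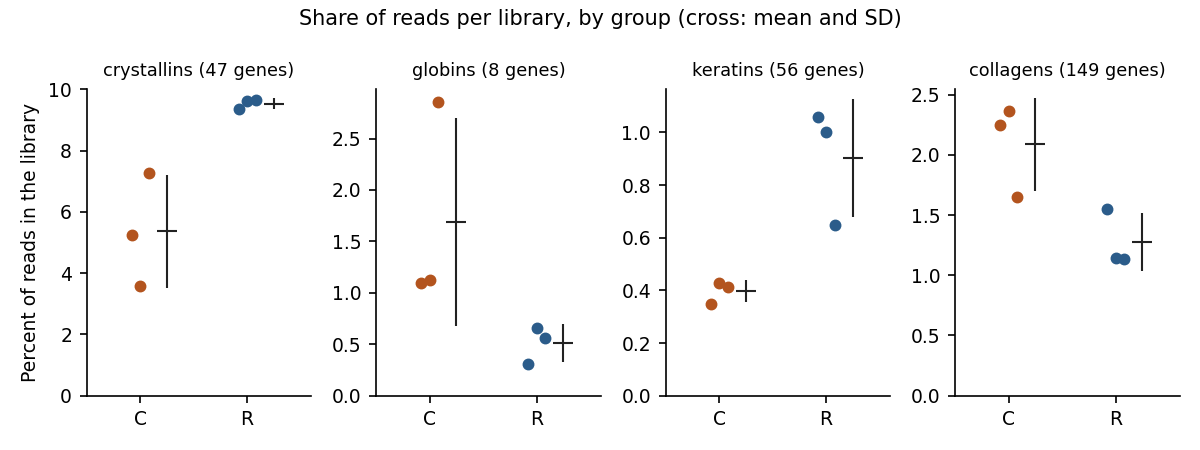
Percent of the reads of each library that fell in crystallin, globin, keratin and collagen genes. Points are libraries and crosses are group means with SD; in each panel all 3 C libraries lie on 1 side of all 3 R libraries.

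Genes listed for bipolar, amacrine and horizontal cells, the retinal interneurons between photoreceptors and ganglion cells, were lower in C. Of 40 tested, 15 fell and none rose, with the same counts adjusted over the list alone, and the mean log2 fold change was -0.54. Whole eyeballs were measured, so this fall cannot be placed in the retina or in these cells. Camera gave an adjusted p of 6.23e-06 (4.75e-07 to 0.000196 over the other settings with that correlation), fry gave 0.0379, and the adjusted p = 0.677 with an estimated correlation. The transcription factor gene tfap2a, used in amacrine and horizontal cells, had 10.3 ± 0.172 FPKM in C and 26.3 ± 1.23 in R (log2 fold change -1.28, SE 0.10, limma adjusted p = 0.000327). A copy of the ON bipolar channel gene trpm1 had 9.91 ± 1.19 FPKM in C and 28.4 ± 4.3 in R (-1.42, SE 0.15, limma adjusted p = 0.00104), with sums of 88.1 ± 9.41 and 117 ± 11.3.

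Cone phototransduction genes were on balance higher in C, with 10 of 30 rising and 4 falling (14 and 6 adjusted over the list alone) and a mean log2 fold change of 0.53. Camera gave an adjusted p of 0.000341 (2.96e-05 to 0.0248 over the other settings with that correlation), and the adjusted p = 0.786 with an estimated correlation. The list was highest in C3 (0.55 around the mean of all libraries, against 0.15 in C1 and 0.10 in C2). Without C3 the mean was 0.39 and the adjusted p 0.0248, the highest of that range. A copy of pde6h, the inhibitory subunit of the cone phosphodiesterase, had 961 ± 234 FPKM in C and 83.7 ± 8.99 in R (log2 fold change 3.48, SE 0.19, limma adjusted p = 4.51e-05). The cone channel subunit gene cngb3 had 42.9 ± 5.34 FPKM in C and 9.07 ± 1.35 in R (2.13, SE 0.15, limma adjusted p = 0.000157). Rod phototransduction was not called (7 rose, 5 fell of 36, camera adjusted p = 0.315), although the S-arrestin gene saga rose from 527 ± 40.2 FPKM in R to 2372 ± 82.5 in C (2.17, SE 0.13, limma adjusted p = 6.8e-05).

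Extracellular matrix lists were called higher in C, but this held for C1 and C2 and not for C3. Of 100 genes of proteoglycans and other matrix, 25 rose and 4 fell (27 and 6 adjusted over the list alone), with a mean log2 fold change of 0.22. Camera gave an adjusted p of 0.000701 (1.89e-05 to 0.0223 over the other settings with that correlation), and the adjusted p = 0.786 with an estimated correlation. The mean of this list was 0.11 without C2 and 0.36 without C3. C3 (-0.17 around the mean of all libraries) lay below R1 (0.01) and R2 (-0.16) and level with R3 (-0.18). The 2 members with the smallest p were copies of sparc, a collagen-binding matrix protein, on chromosome 39 that went in opposite directions. The copy at 27599021 to 27604524 had 23.4 ± 2.65 FPKM in C and 282 ± 96.2 in R (log2 fold change -3.49, SE 0.23), and the copy at 28028776 to 28035142 had 357 ± 40.8 in C and less in R (3.82, SE 0.35). Over all copies the sums were 1160 ± 80.6 FPKM in C and 791 ± 209 in R.

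Of 63 matrix remodelling genes, 15 rose and 4 fell in C, with the same counts adjusted over the list alone, and the mean log2 fold change was 0.19 (camera adjusted p = 0.00436, and adjusted p = 0.786 with an estimated correlation). Its range over the other settings with the preset correlation was 0.000511 to 0.0512, the highest without C2, where the mean was 0.06, while the mean was 0.33 without C3. C3 (-0.18) lay among the R libraries. A copy of the metalloproteinase inhibitor gene timp2 rose from 11.6 ± 1.23 FPKM in R to 30.5 ± 0.719 in C (1.33, SE 0.12; sums 153 ± 10.4 and 196 ± 16.3), and a copy of the collagenase gene mmp13 fell from 39.8 ± 15.1 in R to 4.79 ± 0.938 in C (-2.75, SE 0.29). Of 88 collagen genes, 16 rose and 9 fell (18 and 9 adjusted over the list alone), with a mean of 0.15 (camera adjusted p = 0.0022, and adjusted p = 0.892 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.0501) and without C2, where the mean was -0.03 (adjusted p = 0.0614), and the lowest over those settings was 7.66e-06. The mean was 0.38 without C3, 0.25 without R1 and 0.10 without R3. C3 (-0.37) lay below every R library (-0.19 to 0.12). The 2 collagen members with the smallest p were fragments matched to col6a3, a chain of the microfibrillar collagen VI. Both fell, from 29.2 ± 7.15 to 1.33 ± 0.105 FPKM and from 5.7 ± 0.866 to 0.219 ± 0.379. The first lies near the ppn model on chromosome 38 and is described as a collagen alpha-6(VI)-like chain, so its name is uncertain. The sums over the name, which include it, were 153 ± 13.2 in R and 102 ± 36.0 in C. Collagens took 2.09% ± 0.386 of reads in C and 1.27% ± 0.239 in R (n = 3 each, exact permutation p = 0.1).

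Pigment and muscle lists passed the test narrowly. Of 42 melanin genes, 8 rose and 3 fell in C (11 and 6 adjusted over the list alone), with a mean log2 fold change of 0.22 (camera adjusted p = 0.0424, and adjusted p = 0.786 with an estimated correlation). Over the other settings with the preset correlation it ranged from 0.00501 to 0.126, and it missed the threshold in 8 of them. These were quantile normalization (0.0949), the median ratio set to 0 (0.0624), no low-value filter (0.0569), a mean of at least 5 FPKM (0.126), limma-voom (0.0522), and the fits without C2 (0.0889), C3 (0.0831) or R1 (0.125). A copy of tyr, encoding tyrosinase, the first enzyme of melanin synthesis, had 23.4 ± 10.9 FPKM in C and 1.57 ± 0.731 in R (SE of the log2 fold change 0.32, limma adjusted p = 0.000781). The melanosomal exchanger gene slc24a5 had 4.71 ± 0.43 FPKM in C and 1.91 ± 0.276 in R (0.97, SE 0.16).

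Of 93 skeletal muscle genes, 10 rose and 3 fell in C, with the same counts adjusted over the list alone and a mean of 0.18 (camera adjusted p = 0.0242, and adjusted p = 0.892 with an estimated correlation). Without C2 the mean was -0.12 and the adjusted p 0.877, in a range from 1.81e-06 over the other settings with the preset correlation. With all libraries the call was also lost with quantile normalization (0.0949), the median ratio set to 0 (0.0624), no low-value filter (0.101), a mean of at least 5 FPKM (0.108) and limma-voom (0.0566). Without C3 the mean was 0.53. C3 (-0.61) lay below every R library (-0.11 to -0.08). The slow troponin gene tnnt1 nonetheless rose from 54.4 ± 6.76 FPKM in R to 593 ± 138 in C (3.40, SE 0.18), and a copy of the slow myosin gene myh7 from 7.01 ± 1.8 to 40.5 ± 12.6 (2.35, SE 0.26).

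Red blood cell genes were higher in C, with 8 of 24 rising and none falling (11 and 0 adjusted over the list alone) and a mean log2 fold change of 0.84. Camera gave an adjusted p of 4.73e-05 (1.41e-06 to 0.00165 over the other settings with that correlation), and the adjusted p = 0.786 with an estimated correlation. The erythroid heme synthesis gene alas2 had 66.3 ± 41.5 FPKM in C and 6.89 ± 2.54 in R (log2 fold change 2.97, SE 0.40, limma adjusted p = 0.0025). Its C mean rested much on C3, at 114 FPKM against 44.3 in C1 and 40.4 in C2, and without C3 it stayed called (adjusted p = 0.00209, in a range of 0.00209 to 0.0235 over the other settings). The carbonic anhydrase gene cahz had 122 ± 46.1 FPKM in C and 51.7 ± 5.67 in R (1.16, SE 0.24, limma adjusted p = 0.0148), and it missed the threshold without R1 (0.0574) and without R2 (0.0546), in a range of 0.00762 to 0.0574 over all settings. Globins took 1.69% ± 1.01 of reads in C and 0.509% ± 0.184 in R (n = 3 each, exact permutation p = 0.1), with 1.09% in C1, 1.12% in C2 and 2.85% in C3.

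Energy metabolism lists were higher in C. Of 62 genes of the mitochondrial respiratory chain, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a mean log2 fold change of 0.36 (camera adjusted p = 2.26e-08, and adjusted p = 0.786 with an estimated correlation). Besides cox6a1, a copy of the ATP synthase gene atp5f1b rose from 21.7 ± 7.79 FPKM in R to 53.5 ± 5.79 in C (1.31, SE 0.23). Of 70 glycolysis and hypoxia genes, 20 rose and 3 fell (26 and 4 adjusted over the list alone), with a mean of 0.24 (camera adjusted p = 0.000171, and adjusted p = 0.677 with an estimated correlation). The lactate exporter gene slc16a3 rose from 21.7 ± 4.27 FPKM in R to 54.7 ± 2.35 in C (1.31, SE 0.15). A copy of the hypoxia-inducible gene higd1a fell from 7.77 ± 1.08 FPKM in R to 0.103 ± 0.0473 in C (-2.99, SE 0.17), while another copy changed in the opposite direction and the sums were 36.7 ± 2.71 and 51.8 ± 6.87. Over the other settings with the preset correlation, adjusted p ranged from 1.47e-10 to 0.00189 for the respiratory chain and from 6.38e-05 to 0.0127 for glycolysis and hypoxia.

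Circadian clock genes moved in both directions, with 26 of 75 rising and 10 falling in C (28 and 12 adjusted over the list alone) and a mean of 0.17. C3 (0.02 around the mean of all libraries) lay below R3 (0.04). Camera gave an adjusted p of 0.00329, which was 0.0566 with quantile normalization in a range from 0.000111, and the adjusted p = 0.786 with an estimated correlation. The clock repressor gene ciarta rose from 4.45 ± 0.966 FPKM in R to 23.9 ± 1.96 in C (SE of the log2 fold change 0.16, limma adjusted p = 0.000209), and a copy of the repressor gene nr1d1 (REV-ERB alpha) from 15.1 ± 1.23 to 47.3 ± 4.74 (1.59, SE 0.12, limma adjusted p = 0.000281). Of 39 heat shock and unfolded protein genes, 10 rose and 1 fell, with the same counts adjusted over the list alone and a mean of 0.29. Camera gave 0.00245 (0.000795 to 0.0363 over the other settings with that correlation), and the adjusted p = 0.677 with an estimated correlation. The stress-induced gene ddit4l had 25.1 ± 3.89 FPKM in C and 11.3 ± 1.83 in R (1.08, SE 0.16), and chac1, a glutathione-degrading enzyme gene, 268 ± 10.3 in C and 112 ± 40.4 in R (1.31, SE 0.23).

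**Figure D4:**
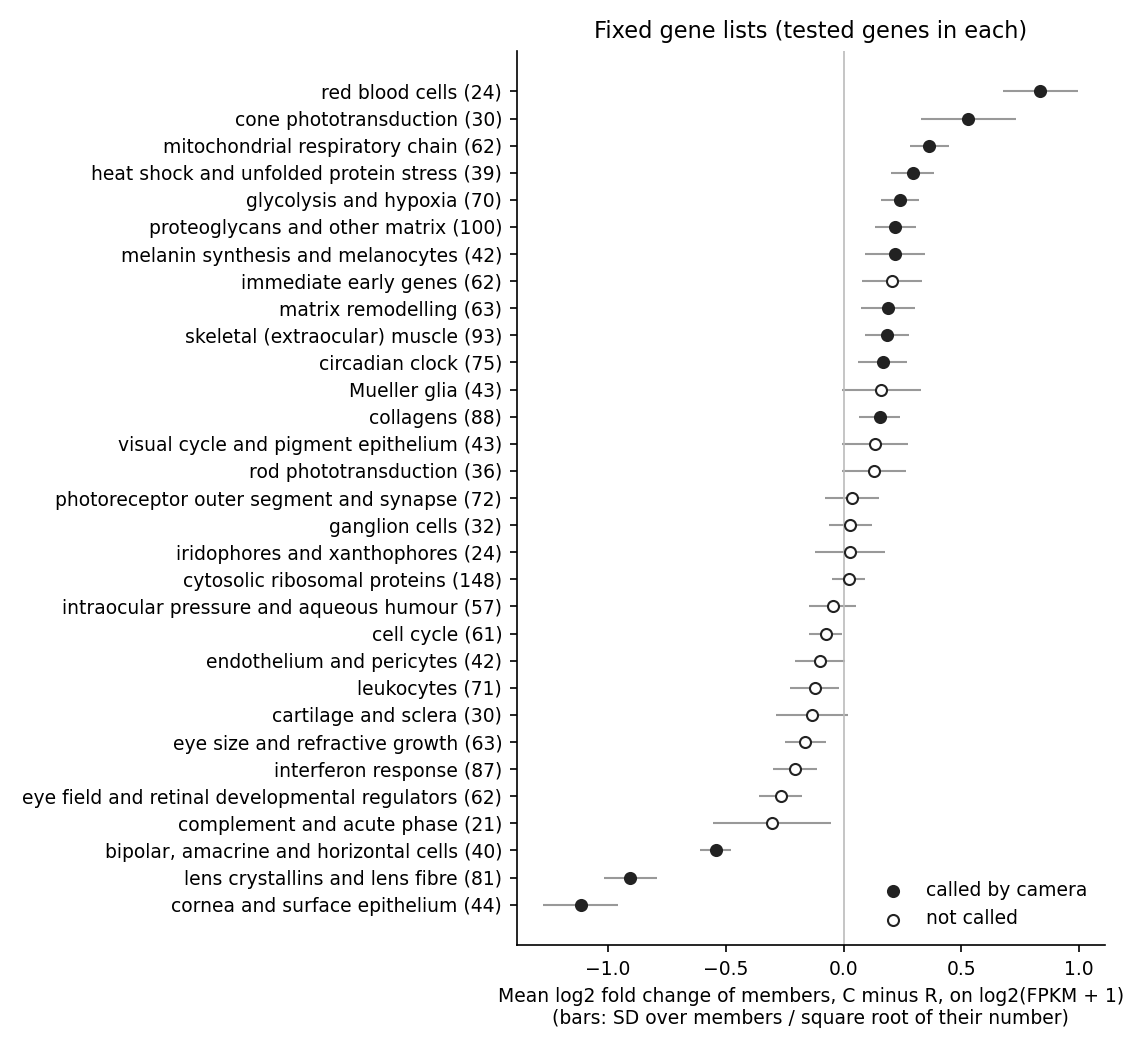
Mean log2 fold change (C minus R) of the members of each of the 31 lists on the log2(FPKM + 1) scale, with bars for the SD over members divided by the square root of their number; filled points were called by camera with the preset correlation. The lens, cornea and interneuron lists lie lowest (-0.90, -1.12 and -0.54) and the red blood cell list highest (0.84).

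None of the 14 calls held with an estimated correlation, and the other 17 lists were not called by camera. For retinal lists, the counts were 16 risen and 10 fallen of 72 photoreceptor outer segment and synapse genes (17 and 11 adjusted over the list alone, camera adjusted p = 0.315), 6 and 7 of 43 visual cycle and pigment epithelium genes (8 and 7, 0.315), 4 and 4 of 32 ganglion cell genes (5 and 5, 0.513) and 12 and 10 of 43 Mueller glia genes (15 and 11, 0.0819). Mueller glia passed the threshold as higher in C without C1 (adjusted p = 0.0195), with same-name genes summed (0.0225) and with exact symbols (0.0429), in a range of 0.0195 to 0.438 over the other settings. For rods the counts adjusted over the list alone were 7 and 5. A copy of guca1a, an activator of photoreceptor guanylate cyclase, fell from 49.1 ± 6.25 FPKM in R to 9.79 ± 1.18 in C (-2.21, SE 0.14), with other copies going both ways and sums of 419 ± 68.2 and 541 ± 158. A copy of rlbp1, the retinaldehyde-binding protein gene of pigment epithelium and Mueller glia, rose from 4.23 ± 1.07 to 81.5 ± 43.4 (3.88, SE 0.33), while its 2 other tested copies fell and the sums were 302 ± 33.0 in R and 243 ± 80.9 in C. A minor copy of the melanopsin gene opn4a had 0.884 ± 0.282 FPKM in C and 2.6 ± 0.102 in R (-0.94, SE 0.18). The sums over the opn4a copies were 54.8 ± 8.92 in C and 56.5 ± 8.21 in R.

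Of 62 eye field and retinal developmental regulators, 11 rose and 20 fell (12 and 25 adjusted over the list alone, camera adjusted p = 0.0803, and 0.0417 to 0.329 over the other settings). The list was called lower in C with quantile normalization (0.0417), the median ratio set to 0 (0.0461) and exact symbols (0.0474). Among them pax6a, a master regulator of eye formation, fell from 43.8 ± 6.18 FPKM in R to 13.8 ± 2.04 in C (-1.60, SE 0.15, limma adjusted p = 0.000689), and 4 of its 5 other tested copies fell too. Of 63 genes of eye size and refractive growth, 6 rose and 9 fell (7 and 9, 0.938), and a tgfb2 copy had 3.8 ± 0.458 FPKM in R against 1 read in C, a ratio of 187 (95% exact counting interval 33.1 to 7416), with another copy changed in the opposite direction and sums of 12.4 ± 1.97 and 15.2 ± 2.16. Of 57 genes of intraocular pressure and aqueous humour, 9 rose and 12 fell (13 and 15, 0.54), and ptgds, a prostaglandin synthase gene, rose from 1.61 ± 0.302 FPKM in R to 7.57 ± 1.48 in C (1.71, SE 0.18). Of 30 cartilage and sclera genes, 3 rose and 5 fell (5 and 6, 0.811), and the cartilage matrix gene ucma rose from 41.4 ± 5.77 to 157 ± 19.6 (1.90, SE 0.15). Of 24 iridophore and xanthophore genes, 3 rose and 4 fell (4 and 4, 0.5), and gch1, the first enzyme gene of pteridine synthesis, fell to 5.14 ± 0.411 FPKM in C at this copy (-0.97, SE 0.13). Another gch1 copy rose, and the sums were 171 ± 67.1 in C and 130 ± 39.7 in R.

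Among immune and vascular lists, 10 rose and 12 fell of 71 leukocyte genes (13 and 13 adjusted over the list alone, camera adjusted p = 0.483), 1 and 4 of 21 complement genes (2 and 5, 0.315), 7 and 17 of 87 interferon response genes (8 and 17, 0.749) and 4 and 8 of 42 endothelium and pericyte genes (4 and 8, 0.789). A copy of the macrophage gene mpeg1 had 2.41 ± 0.535 FPKM in R and no read in C, at least 69.0-fold lower against the floor, with sums over its copies of 30.1 ± 5.85 in R and 31.9 ± 6.98 in C. A copy of the MHC class I gene mhc1uba had 12.4 ± 2.8 FPKM in R and no read in C, at least 233-fold lower. The sums over its copies were 18.05 ± 1.32 FPKM in R and 2.67 ± 0.52 in C. Complement factor D, cfd, fell from 260 ± 53.5 FPKM in R to 66.1 ± 15.5 in C (-1.96, SE 0.20), and a copy of the tight junction gene cldn5a from 27.4 ± 5.87 to 4.84 ± 1.89 (-2.32, SE 0.26). This cldn5a copy is described as claudin-4-like, so its name is uncertain. The only other tested model named cldn5a rose.

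Of 62 immediate early genes, 11 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0732). They passed as higher in C without C3 (0.000784) and without R3 (0.044), in a range of 0.000784 to 0.438. A copy of the phosphatase gene dusp2 fell from 42.2 ± 9.42 FPKM in R to 5.75 ± 1.8 in C (-2.69, SE 0.24), while its copies summed to 78.4 ± 13.9 and 78.5 ± 26.6. Of 61 cell cycle genes, 4 rose and 2 fell (1 and 2, 0.689), and the dUTPase gene dut had 6.49 ± 0.352 FPKM in R and no read in C, at least 65.5-fold lower. Of 148 cytosolic ribosomal protein genes, 6 rose and 5 fell (6 and 5, 0.505), with rps3a described above. The median, the mean and the camera direction differed in sign for 7 of the lists that were not called: rods, outer segment, cartilage, leukocytes, intraocular pressure, cell cycle and ribosomal proteins.

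The 57 named genes with a test kept their direction under each pseudocount, scaling, filter, block and leave-one-out fit in which they were tested and under limma-voom, and in these fits only cahz lost its call at an adjusted p under 0.05. Of the 57, 8 were not tested with a mean of at least 5 FPKM, since they lay below it. At the stricter limits opn4a (0.0106) and cahz (0.0148) missed an adjusted p of 0.01, and opn4a (-0.94), slc24a5 (0.97) and gch1 (-0.97) missed the 2-fold minimum. Where gene names are shared, the values belong to the single model named. Of the 55 named models with a symbol, 45 had another tested model of the same name, which changed in the opposite direction for 18 and in the same direction for 17.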

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

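The added fits, limma-voom on recovered reads and the sums over same-name genes, were chosen after the result was seen. The counts of changed, higher and lower genes were 2688, 1222 and 1466 at an adjusted p under 0.01; 3195, 1354 and 1841 with a 2-fold minimum; 3670, 1959 and 1711 with a mean of at least 5 FPKM, where fewer genes are tested; and 3863, 1659 and 2204 with same-name genes summed, again over fewer tests. Leaving out 1 library gave 3557 to 6404 changed, 1628 to 3163 higher and 1929 to 4056 lower genes. Genes changed at least 2-fold numbered 3195, 1451 with a mean of at least 5 FPKM, 1611 with same-name genes summed, and 2566 to 3492 with 1 library left out. Limma-voom called 7853 genes, 6145 of them shared in the same direction. Camera called 14 lists, 0 with an estimated correlation, and 10 to 15 with 1 library left out. Fry, which tests whether a set moves 1 way and compares it with no other genes, called 1. The camera fit with an estimated correlation differed from the main one only in that setting, so the 14 calls rest on the preset of 0.01. Why fry called fewer lists was not tested. Without C2 the mean of the collagen list turned to -0.0318 and that of skeletal muscle to -0.12; without C3 they were 0.38 and 0.53. The first component held 84.8% of the variance over the 1000 most variable genes. With same-name genes summed, all 14 lists kept their call.

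No clear pairing by replicate number was seen. Deviations from the group means correlated by -0.01, 0.10 and 0.04 between same-numbered C and R libraries, and by -0.11 to 0.07 between differently numbered ones. So few libraries cannot exclude a shared day or batch. As a block, the replicate number gave 5971 changed genes, 5494 shared in the same direction, and 14 lists called. The alternatives planned for count tables were not run, since the files hold FPKM.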

Other observations

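The tests of chance splits, of lens tissue, of scaling, of copies on the same chromosome and of neighbouring genes, and the pathway test, were chosen after related results were seen; the predictions for copies on other chromosomes and for clock phases were written before those tests were run. Among 149 KEGG pathways of the files' own annotation with at least 15 tested genes, camera called 10 higher and 2 lower in C, and none with an estimated correlation. Oxidative phosphorylation led those that rose, with 43 of 221 genes rising and 9 falling (mean log2 fold change 0.24, adjusted p = 3.55e-08, and adjusted p = 0.984 with an estimated correlation). Phototransduction (18 rose and 8 fell of 78, adjusted p = 0.0341) and tyrosine metabolism (9 and 2 of 40, 0.0342) were also called, with adjusted p of 0.994 and 0.981 with an estimated correlation.

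Both pathways that were lower in C were of polyunsaturated fatty acids. In linoleic acid metabolism 10 of 31 genes fell and 1 rose (mean -0.66, adjusted p = 0.0197), and in alpha-linolenic acid metabolism 8 of 32 fell and 1 rose (mean -0.52, adjusted p = 0.0341). Each had an adjusted p = 0.95 with an estimated correlation. The members that fell, named after their values were seen, included copies of pla2g4c, a cytosolic phospholipase A2, in both pathways. Copies of cyp2j cytochromes fell in the first, and fads2, a fatty acid desaturase gene, in the second.

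Genes seen in 1 group only were a further feature. With a mean of at least 5 FPKM in 1 group and no read in any library of the other, 17 genes were seen in C only and 42 in R only. Of these, 17 and 35 had at least 1 FPKM in all 3 libraries of their group.

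The real split into C and R gave 6864 changed genes by limma. The 10 splits of 3 against 3 are too few for a share under 0.05: 1 split, the real one, reached that count. The highest of the others was 0, with at most 1169 genes at an unadjusted p under 0.05 and 0 by limma-voom. Each of the others mixes C with R libraries, so the difference between the letters widens the spread within its groups and lowers its count. These splits therefore do not show what chance would give.

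Many of the largest changes were in genes with same-name copies. If reads only moved between near-identical copies, copies should move in opposite directions. On other chromosomes, which would include the duplicated genome, 34.2% of the 111 called copies of genes changed at least 4-fold went the opposite way (95% exact interval 25.5% to 43.8%), but 71.0% of the 383 copies there were not called, among them any abundant copy that gained or lost few reads, so this share decides nothing. On the same chromosome, where 34.8% were not called, 61.0% of 118 called copies went the opposite way (51.6% to 69.9%). This interval treats copies as independent, but some genes enter more than once and some neighbouring genes have neighbouring copies. The opposite copies that prompted the test are counted too, so it is not settled that opposite moves outnumber moves in the same direction. For marcksl1a, an opposite pair, the copy Cau.38G0011250, chosen after its values were seen, had 1.03 ± 0.0672 FPKM in C and 41.6 ± 2.58 in R. A candidate explanation is that these model pairs stand for alleles or local duplicates that differ between the 2 stocks, so that reads fall on 1 or the other, which was not tested further.

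The lower lens signal may come from a lower share of lens tissue in the C eyeballs or from lower expression in lens cells. Of the 20 most abundant lens list members all 20 lay below the median of all genes, with an SD of 0.34 around a median log2 fold change of -0.89, as a share would need. Over all 81 members the SD was 1.00, so a common shift of every member was not seen, and the 2 readings cannot be told apart. Scaling by abundant genes is argued against, since the list mean was -0.82 with the median log2 ratio set to 0. Lens and surface lists did not vary together among the C libraries: relative to the mean of all 6, the lens list was lowest in C2 (-0.86) and the cornea list in C3 (-0.91).

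A different time of day at sampling may account for part of the clock changes. The per, nr1d, tef, hlf and ciart genes had a median log2 fold change of 0.77 (26 genes, 17 rose and 0 fell), and the bmal, clock, npas2 and nfil3 genes, which peak at the opposite phase, -0.21 (15 genes, 1 rose and 4 fell), a difference of 0.98. Those that fell were 3 clock copies and nfil3-2, while nfil3-6 rose and neither bmal1b (0.18) nor arntl2 (0.43) was called. Of the 10 clock list genes that fell, 5 were rorb copies (-1.96 to -1.29) that were placed in neither phase. The labels give no time of sampling, and 1 farm per group means that light regime, stock and eye phenotype stay open and untested.

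Changed genes also lay beside each other on chromosomes. Over 22624 adjacent pairs of tested genes with unlike names, 702 pairs changed in the same direction, 1.52 times the mean of 463 in 1000 shuffled orders (at most 523), while 402 changed in opposite directions against 444. This is consistent with blocks of linked genes that differ between the 2 stocks. Neighbours that are expressed together in the same tissue would give the same excess, which was not tested.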
